A study of Mus musculus with 4 samples.

How the data were processed

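Xenium transcript imaging was carried out by the authors on en face cryosections of wild-type mouse retina, 20 µm thick, with a custom panel of 300 genes. Per the file headers, the deposited table gives puncta counts per cell, whole numbers of decoded transcripts for each gene, together with the retina, slide, section, position, volume and type of each cell. The counts were used as deposited, with no normalization applied beforehand. How cells were segmented, which cells were kept and how types were assigned is not given in the sources used here. A check of the values showed that every cell was of class RGC and held at least 100 puncta, so shares below are shares of RGCs and not of all retinal cells. The 4 deposited samples are pairs of slides, and no label ties a slide of the table to a sample. The replicate was therefore the retina named in the table (n = 5), and the 41 sections lie within retinas. Of the 8 slides, 1 holds sections of retinas 4 and 5 and 1 of retinas 3 and 5, so these retinas share slides. Sections held 19 to 10883 cells.

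Positions scaled to a circle by the authors were used as given. The radial axis was split at 0.5 into centre and periphery, and the X and Y axes at 0. The labels give no anatomical direction for either axis. Volumes and slide positions have no stated unit.

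Counts were summed per retina and side, gate or type. They were fitted with edgeR 4.0.16 (quasi-likelihood, with the retina as a block, TMM scaling and filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes of each contrast and a threshold of 0.05. For genes within types, the adjustment ran over all type-gene pairs of an axis. Sums needed at least 50 cells within types and 20 cells in the type marker fit. Gates compared cells with at least 1 punctum of Opn4, Eomes, Foxp2, Neurod2 or Spp1 with cells without one, leaving out the gate gene. Another 4 planned gate genes are not on the panel, and 1 further planned gate is not reported here. Co-detection used each cell thinned to 100 puncta, 1 odds ratio per retina and pair with 0.5 added to each count, and an exact two-sided sign-flip permutation test over the retinas. Type shares along the axes had the same exact test as planned, and edgeR on cell counts was added after the data were seen. That fit scaled by the cells per side, with no filter. The same-mix comparison gave each type with at least 20 cells per side the same weight on either side, its cells over both sides, and used limma 3.58.1 on the 5 differences. DESeq2 1.42.0 served as the alternative tool. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

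The comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. That rule names up to 12 genes in each direction, with the largest changes among those past the threshold that changed the same way in every retina, at no fewer than 100 puncta. The type families and the counts of types per gene were chosen after the data were seen, as were Ndnf in 22_M5 and Calb1 in 24_Novel. Lists held the genes of ipRGCs (4 on the panel), alpha RGCs (5), Foxp2 RGCs (3), T-RGCs (2), N-RGCs (3), W3 and small RGCs (5), axis genes (1), voltage-gated channels (58, by symbol, which takes in the channel partners and the non-coding Kcnq1ot1), neuropeptides and hormones (7) and RGC transcription factors (16). Further lists held the markers of RGCs (6), amacrine (14), bipolar (12) and horizontal cells (5), rods (3), cones (3), Müller glia (6), astrocytes (2), microglia (2), endothelium (1) and pericytes with smooth muscle (2). No gene of the direction-selective list or the pigment epithelium list is on the panel.

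Along the radial axis, 1 of the 2 T-RGC genes (Jam2), 1 of the 5 W3 genes (Lypd1), none of the 3 Foxp2-list genes and not Isl2 passed in edgeR, the same adjusted over the list alone. Of the 6 RGC markers Nefh alone passed, along X. For neuropeptides 2 were higher and 1 lower along the radial axis, and 3 and 1 adjusted over the list alone.

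Medians of 285 to 326 puncta per cell over 300 genes leave most genes at 0 or 1 punctum in a cell, so single cells were not compared. Error terms are the SE of the fit or the SD between retinas, and the counting intervals given for cone opsins cover counting error only. The gene fits were tested on simulated data with 200 genes changed before the filter, which left 261 genes within 31_M2. The type share fits had 5 of 45 types changed at each fold of 1.2, 1.5 and 2. Each fit had 1 simulated data set, so the shares recovered carry their own chance error. Of 1.2-fold changes 80% were recovered along the radial axis, 72% along Y and 82% along X, and of 1.5-fold changes 98% on the radial axis and all on Y and X. Within 31_M2 50% of 1.2-fold and 77.3% of 1.5-fold changes were recovered, and of type shares along Y 0 of 5 1.2-fold and 80% of 1.5-fold changes. Unchanged types were called in 23.3% of cases along the radial axis and unchanged genes in 10% along X. The sign-flip test gave its smallest p for 5 values of one sign.

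The planned class shares, the comparison of RGCs with other cells and the clustering were left out, as the table holds RGCs alone. The alternatives tried were total puncta scaling, DESeq2, no filter on low counts, no replicate block, leaving out each retina, a gate of 2 puncta, thinned or deposited cells and the outermost regions alone (on X and Y the positions 0.333 or more from 0, on the radius its inner and outer ends of that length). After seeing the data, cells of 200 puncta or more, slide or section blocks, the same mix of types, and the cell count fits were added. The deposited images were not analysed here.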

Results

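Retinal ganglion cells (RGCs), the output neurons of the retina, were mapped in wild-type C57BL/6 mice with Xenium, an imaging assay that decodes single transcripts as puncta inside tissue sections. Retinas were sectioned en face, parallel to the retinal surface, at 20 µm, and probed with a custom panel of 300 genes. The question posed by the design was how the RGC subtypes are distributed over the retina. The deposited table held 131379 cells, all of them called RGCs and each assigned by the authors to 1 of 45 types, from 41 sections on 8 slides. The labels describe 1 group, so the comparisons below lie within retinas: between types, between cells with and without a subclass gene, and between positions. Retina 1 held 35099 cells with 12175542 puncta, retina 2 held 41048 cells with 12879454, retina 3 held 13127 cells with 4048481, retina 4 held 27734 cells with 8580422 and retina 5 held 14371 cells with 4661146. The median per cell was 326, 297, 285, 295 and 304 puncta in retinas 1 to 5. Retinas 3 and 5 held the fewest cells, so their values carry the largest counting error. The labels do not say whether the 5 retinas came from separate animals, so p-values measure only the spread between these retinas.

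The most abundant RGC types belonged to the W3 cells and the Foxp2-expressing F cells. Type 01_W3D1.1 made up 8.88% ± 0.62 of RGCs (SD, n = 5 retinas), 02_W3D1.2 5.33% ± 0.65 and 03_FminiON 5.13% ± 0.65. They were followed by 21_Tbr1_S2 at 4.85% ± 0.21 and by the ON-OFF direction-selective type 16_ooDS_DV at 4.59% ± 0.39. The rarest types were 44_Novel at 0.254% ± 0.058, 35_Novel at 0.310% ± 0.089, 41_AlphaONT at 0.592% ± 0.11 and 40_M1dup at 0.594% ± 0.16. Grouped by the type names, the 4 W3 types made up 19.3% ± 1.1 of RGCs, the 5 F types 12.8% ± 0.58, the 3 ooDS types 11.1% ± 0.72 and the 3 Tbr1 types 8.87% ± 0.23. The 4 alpha types, large cells with thick axons, made up 4.72% ± 0.44. The 4 types grouped by name as intrinsically photosensitive RGCs (ipRGCs: 22_M5, 31_M2, 33_M1 and 40_M1dup) made up 4.32% ± 0.37. Any photosensitive cells under other type names, the alpha names included, are not in that share. The remaining 22 types held the rest. Every type was found in every retina, with 26 cells or more. Shares varied least between retinas for 34_Novel (CV 1.88%) and 06_W3B (2.54%) and most for 35_Novel (28.6%) and 40_M1dup (26.4%). By cell size, 43_AlphaONS cells had a median volume of 915 ± 107 and 45_AlphaOFFT cells of 907 ± 86.5 in the file's units, against 418 ± 28.5 for 01_W3D1.1.

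**Figure D1:**
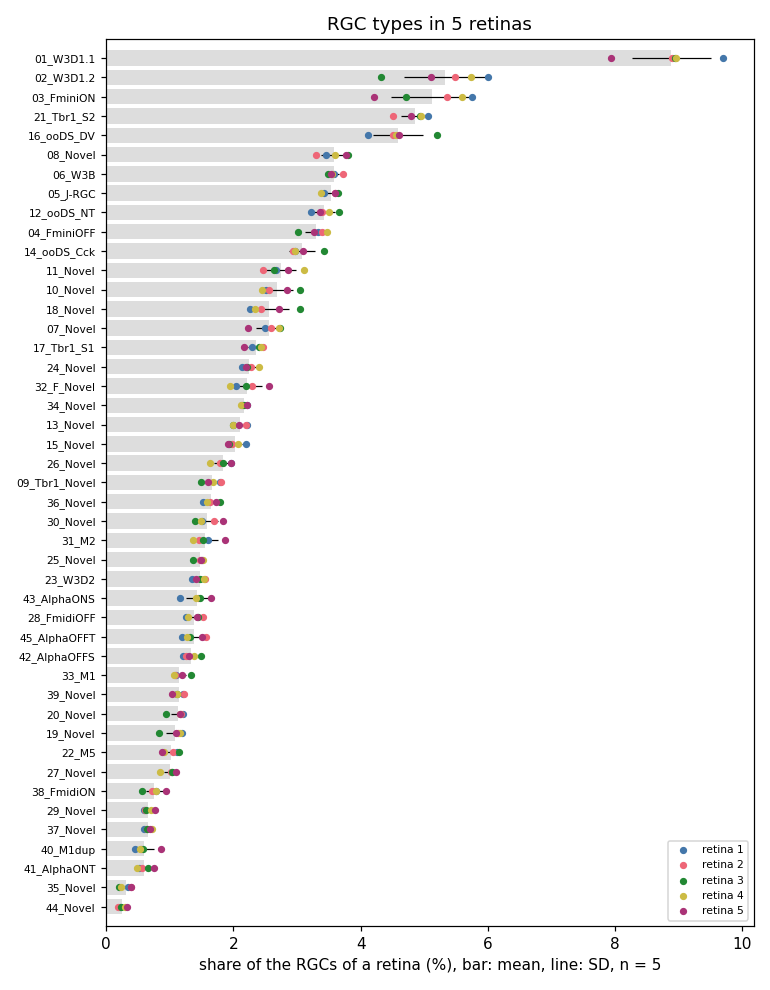
Share of each of the 45 RGC types in percent of the RGCs of a retina, with the mean (bar), the SD (line) and each of the 5 retinas (points). Type 01_W3D1.1 lay highest at 8.88% and 44_Novel lowest at 0.254%.

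Genes were compared type by type against the mean of the other types. Opn4, the gene of the photopigment melanopsin, was higher in 40_M1dup by a log2 fold change of 7.50 ± 0.06 (SE), with 9.25 puncta per cell, in 33_M1 by 6.30 ± 0.07 with 3.59, in 31_M2 by 5.29 ± 0.07 with 1.87 and in 22_M5 by 4.29 ± 0.10 with 0.932. The transcription factor gene Tbx20 was highest in 07_Novel (6.53 ± 0.06), and Zic1, another transcription factor gene, in 06_W3B (6.34 ± 0.05), together with Penk, which encodes the opioid precursor proenkephalin (4.87 ± 0.04). Mmp9, a matrix metalloprotease gene, led 10_Novel (4.61 ± 0.04), 24_Novel (4.31 ± 0.04) and 16_ooDS_DV (3.38 ± 0.04). Tpbg led 34_Novel (5.70 ± 0.06), Cacna1e, a calcium channel subunit, led 11_Novel (5.09 ± 0.06), and Slc17a7, a vesicular glutamate transporter, led 25_Novel (4.41 ± 0.08). Etv1 led 41_AlphaONT (4.97 ± 0.06), Igfbp2 led 42_AlphaOFFS (5.22 ± 0.06), Spp1 (osteopontin) led 43_AlphaONS (5.18 ± 0.05), and Kcnip2, a potassium channel partner, led 45_AlphaOFFT (5.08 ± 0.05). The leading genes of 44_Novel were Tmem119 (5.58 ± 0.20), Sst (5.44 ± 0.42) and Cdh5 (5.10 ± 0.13), of which Tmem119 stands on the microglia list, Sst on the amacrine list and Cdh5 on the endothelial list. In edgeR, 9278 of 13455 type-gene pairs passed an adjusted p of 0.05, 4093 higher and 5185 lower. How the types were assigned is not given, and they can rest on these same genes, so these values describe the types and are not independent findings.

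Taken as families, ipRGC types were highest in Opn4 (6.28 ± 0.05), Tbx20 (4.60 ± 0.06), Prkcq (3.97 ± 0.04) and Eomes (3.69 ± 0.03). They were lowest in Gabra2 (-1.94 ± 0.04), a GABA receptor subunit, and Pou4f3 (-1.63 ± 0.07). Alpha types were highest in Spp1 (4.93 ± 0.03), Etv1 (3.81 ± 0.04) and Coch (3.56 ± 0.04) and lowest in the sodium channel subunit Scn3b (-2.14 ± 0.04). F types were highest in Foxp2 (4.32 ± 0.04) and the glutamate receptor genes Grin3a (2.15 ± 0.03) and Gria1 (1.78 ± 0.04). The Tbr1 types were highest in Rprm (2.51 ± 0.04) and Slitrk6 (2.27 ± 0.05), the ooDS types in Tfap2d (3.25 ± 0.04) and the GABA receptor gene Gabrg3 (2.55 ± 0.03), and the W3 types in Ppp1r17 (1.81 ± 0.04), Isl2 (1.74 ± 0.03) and the potassium channel gene Kcnd2 (1.74 ± 0.03). All 4 measured genes of the ipRGC list were higher in the ipRGC family, all 5 of the alpha list in the alpha family and all 3 of the Foxp2 list in the F family, with the same counts adjusted over the list alone. Of the 5 genes on the W3 list, 3 were higher and 2 lower in the W3 family, also adjusted over the list alone. Of 58 genes whose symbols begin with Kcn, Scn, Cacn or Hcn, 33 were higher and 24 lower in alpha types, led by Scn4b (2.81 ± 0.04), and 15 were higher and 39 lower in ipRGC types, led by Scn9a (1.46), again with the same counts adjusted over the list alone. In the ipRGC family both microglia markers were also higher (Tmem119 2.48, Aif1 1.97), as were the endothelial marker Cdh5 (1.06) and all 6 Müller glia markers (Slc1a3 0.94). The families numbered 255 called genes of 299 for ipRGC, 236 for alpha, 224 for F, 199 for Tbr1, 235 for ooDS and 222 for W3 (edgeR).

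Cells with at least 1 punctum of a subclass gene were compared with cells without one, which asks what goes with that gene without using the types. With Opn4, Prkcq (3.30 ± 0.06), Eomes (2.91 ± 0.04), Tbx20 (2.79 ± 0.04) and Ndnf (2.73 ± 0.04) were higher, and Penk (-1.25 ± 0.04), Pou4f3 (-1.23 ± 0.06), Tfap2d (-1.17 ± 0.07) and Isl2 (-1.11 ± 0.05) were lower. With Eomes, a T-box transcription factor gene, Opn4 (4.19 ± 0.06), Tbx20 (3.86 ± 0.04), Prkcq (2.95 ± 0.06) and Sst, which encodes somatostatin (2.51 ± 0.15), were higher, and Gsg1 (-0.93 ± 0.10) and Vsx1 (-0.73 ± 0.09) were lowest. With the forkhead gene Foxp2, Gria1 (2.01 ± 0.03), Grin3a (1.98 ± 0.03), Npnt (1.92 ± 0.06) and Foxp1 (1.61 ± 0.03) were higher and Spp1 (-1.21 ± 0.07) and Opn4 (-1.13 ± 0.11) lower. With Neurod2, a basic helix-loop-helix factor, Rab3b (1.80 ± 0.08), Penk (1.79 ± 0.02), Slc17a7 (1.60 ± 0.10) and Bhlhe22 (1.53 ± 0.05) were higher and Opn4 (-1.39 ± 0.09) and Spp1 (-1.27 ± 0.07) lower. With Spp1, Etv1 (2.64 ± 0.07), Igfbp2 (2.57 ± 0.07), Kcnip2 (1.95 ± 0.05) and Cdkn1c (1.88 ± 0.05) were higher and Sst (-1.11 ± 0.16) and Gsg1 (-0.79 ± 0.09) lower.

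Genes of the lists fixed beforehand were counted by direction with each gate, with no test of a list as a set. All 3 tested ipRGC genes were higher with Opn4, and all 3 with Eomes, while all 4 were lower with Foxp2 and with Neurod2. All 4 tested alpha genes were higher with Spp1, from Nefh, the neurofilament heavy chain gene, at 0.53 to Kcnip2 at 1.95. The 3 Foxp2-list genes were all lower with Opn4, Eomes, Neurod2 and Spp1, and both tested members, Foxp1 and Ppp1r17, were higher with Foxp2. Of the N-RGC list, Penk was higher with Neurod2 and S100b was not called (0.11). Of the T-RGC list, Jam2 was higher with Foxp2 (0.36) and lower with Neurod2 (-0.31), Spp1 (-0.30) and Opn4 (-0.12). Isl2, the only axis gene on the panel, was lower with Opn4, Eomes, Neurod2 and Spp1 and higher with Foxp2 (0.57). Among the 58 channel-named genes, 39 were higher and 14 lower with Foxp2 (Cacna1i 1.26, Kcnh1 -0.83), 31 and 16 with Neurod2, and 18 and 26 with Opn4. Adjusted over the list alone these counts were the same except 32 higher with Neurod2. The 7 neuropeptide genes gave 4 higher and 2 lower with Eomes, and the 16 RGC transcription factor genes gave 7 higher and 8 lower with Opn4, in both cases the same adjusted over the list alone. Of the 5 horizontal cell markers 4 were higher with Opn4, led by Ndnf, and of the 14 amacrine markers 10 were higher with Foxp2, led by the glycine transporter gene Slc6a9 (0.69), again the same adjusted over the list alone.

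The gates called 199 of 299 genes for Opn4 (100 higher, 99 lower), 234 for Eomes (86 and 148), 230 for Foxp2 (127 and 103), 214 for Neurod2 (94 and 120) and 212 for Spp1 (82 and 130), all in edgeR, so most members of any list would be called. Cells with a gate gene were deeper, with medians of 343 against 301 puncta for Opn4. With 200 of 299 genes changed in simulated data, 49.5% of the unchanged ones were called in the Foxp2 gate and 27.3% in the Eomes gate, against 4.04% for Opn4, 6.06% for Neurod2 and 5.05% for Spp1.

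Most pairs of subclass genes were found together less often than independent detection gives. After thinning each cell to 100 puncta, this held in all 5 retinas for 7 of the 10 pairs of 5 such genes. The lowest log2 odds ratios were -1.26 ± 0.27 (SD, n = 5) for Foxp2 with Neurod2, -1.20 ± 0.42 for Opn4 with Foxp2 and -1.07 ± 0.38 for Opn4 with Neurod2. The other 3 pairs were found together more often in all 5 retinas: Opn4 with Eomes (3.26 ± 0.10), Opn4 with Spp1 (1.30 ± 0.09) and Eomes with Spp1 (0.62 ± 0.07). In the same thinned cells Opn4 was detected in 71.1% ± 11 of 40_M1dup cells and 49.4% ± 3.6 of 33_M1 cells, against 0.317% ± 0.35 of 09_Tbr1_Novel cells, and Spp1 in 94.5% ± 0.83 of 43_AlphaONS cells against 6.78% of 07_Novel cells. The exact two-sided sign-flip permutation test gave p = 0.0625 for each of the 10 pairs, the smallest p that 5 retinas allow, and the same adjusted p over the 10 pairs. When detection required 2 puncta, the 10 means kept their signs but 9 moved by more than the SD, to -3.41 for Opn4 with Foxp2, -3.24 for Neurod2 with Spp1, -2.64 for Foxp2 with Spp1, -2.33 for Foxp2 with Neurod2 and 5.42 for Opn4 with Eomes. In the cells as deposited, Foxp2 with Spp1 lay at -0.54, Neurod2 with Spp1 at -0.42 and Eomes with Foxp2 at -0.46, and Eomes with Neurod2 turned to 0.013.

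**Figure D2:**
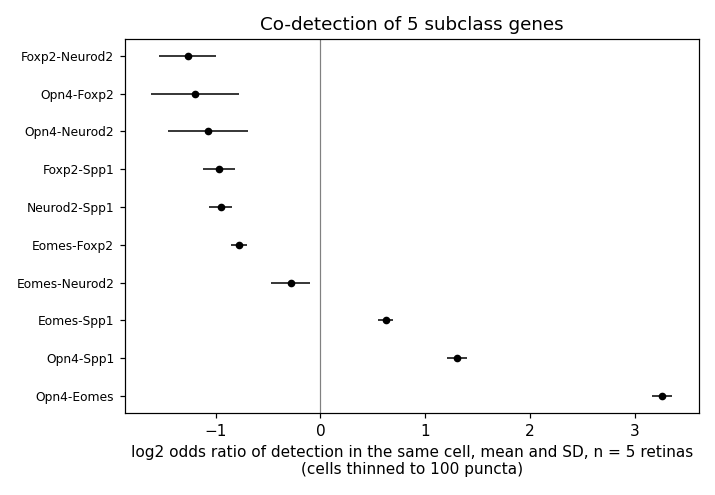
Log2 odds ratio of detecting both genes of a pair in the same RGC, mean and SD of 5 retinas, in cells thinned to 100 puncta. Values right of 0 are pairs found together more often than independent detection gives, with Opn4 and Eomes highest at 3.26.

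From the centre to the periphery of the retina, 3 of the 4 ipRGC types and the 4 alpha types took a larger share. The peripheral share of 40_M1dup was 0.718% ± 0.23 (SD, n = 5) against 0.429% ± 0.16 centrally, a log2 ratio of 0.71 ± 0.15 (SE), and 33_M1 (0.51 ± 0.10), 31_M2 (0.37 ± 0.08), 42_AlphaOFFS (0.54 ± 0.10), 43_AlphaONS (0.44 ± 0.10), 41_AlphaONT (0.54 ± 0.17), 45_AlphaOFFT (0.25 ± 0.09) and 44_Novel (0.85 ± 0.18) were also higher peripherally. The ipRGC type 22_M5 was not called (-0.04 ± 0.11). Of the alpha types 42_AlphaOFFS was higher in all 5 retinas, and the other 3 were higher in 4 and lower in retina 3. With the section as a block, added after seeing the data, 17 of the 19 called types stayed called, 40_M1dup at 0.44 ± 0.16, without 45_AlphaOFFT (0.14 ± 0.07) and 18_Novel (0.12 ± 0.06). The share of 35_Novel was lower in the periphery (-0.78 ± 0.17, 0.262% ± 0.087 against 0.416% ± 0.15), as were those of 26_Novel (-0.36 ± 0.09), 12_ooDS_NT (-0.23 ± 0.06) and 05_J-RGC (-0.23 ± 0.06). Among genes, Opn4 was higher peripherally (0.55 ± 0.07), with 0.207 ± 0.011 against 0.141 ± 0.024 puncta per cell, and so were Sst (1.04 ± 0.20), Fxyd6, a regulator of the sodium pump (0.49 ± 0.08), and the rod transducin gene Gngt1 (0.32 ± 0.06). Neurod2 (-0.33 ± 0.06), the intermediate filament gene Prph (-0.29 ± 0.05), Lypd1 (-0.29 ± 0.06), Cxcl14 (-0.26 ± 0.05), the acetylcholine synthesis gene Chat (-0.26 ± 0.05) and Penk (-0.25 ± 0.03) were lower peripherally.

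Centre and periphery were split at the middle of the scaled radius, with 46830 and 84549 cells and median depths of 300.6 and 302.3 puncta. In edgeR, 20 of 300 genes were called, 10 higher and 10 lower, each in one direction in all 5 retinas. Over all 300 genes the retinas were less alike. Radial gene differences of retinas 2, 4 and 5 had Spearman correlations of 0.64 to 0.81, while retina 1 lay at -0.10 to 0.12 against the others. In radial type shares retina 3 lay at 0.12 to 0.27 against the others. The named genes also included Cacna2d4 (0.44 ± 0.10), Cd24a (0.27 ± 0.05), Spc25 (0.19 ± 0.04), Glra1 (0.19 ± 0.04), Eomes (0.16 ± 0.03) and Igf1 (0.15 ± 0.03) on the higher side and Jam2 (-0.21 ± 0.03), Pcdh8 (-0.16 ± 0.03), Kcnq3 (-0.14 ± 0.03) and Kcnn2 (-0.13 ± 0.03) on the lower. Of the 4 ipRGC genes 3 were higher (Opn4, Eomes, Igf1), and 2 of the 3 N-RGC genes were lower (Neurod2, Penk), with the same counts adjusted over the list alone. None of the 5 alpha genes was called in edgeR, 1 was called adjusted over the list alone, and Spp1 stood at 0.36. Among the 58 channel-named genes 1 was higher and 2 lower over the panel, and 0 of them were called adjusted over the list alone. Of the 16 RGC transcription factor genes Eomes was higher and Neurod2 lower. With the same mix of types on both sides, limma called 17 genes, 13 of them shared with the first count. Fxyd6 (0.48 ± 0.08) and Sst (0.93 ± 0.20) stayed called there, and Opn4 fell to 0.17 ± 0.06 with an adjusted p of 0.178. The exact sign-flip test on type shares, whose smallest p is 0.0625, gave that p for the 16 types that moved one way in all 5 retinas. The edgeR fit on cell counts, added after seeing the data, called 19 types, 12 higher and 7 lower, and 12 types without retina 4. In simulated data that fit called 7 of 30 unchanged types (23.3%), so some of the 19 may be false calls. The gene count rested on single retinas: it was 53 without retina 1, 3 without retina 2, 2 without retina 4 and 10 without retina 5, with only Opn4 and Fxyd6 called in each of the 5 fits. DESeq2 called 44 genes, and edgeR without the retina as a block called 1. With the slide within retina as a block, added after seeing the data, 12 of the 20 genes stayed called: Cacna2d4 fell to 0.11 ± 0.20, Gngt1 to 0.13 ± 0.09, Cd24a to 0.21 ± 0.09, Glra1 to 0.11 ± 0.06, Pcdh8 to -0.07 ± 0.06, Kcnq3 and Kcnn2 to -0.06, and Neurod2, at -0.34 ± 0.11, had an adjusted p of 0.081. The section as a block kept 13 of the 20, without the first 7 of these.

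**Figure D3:**
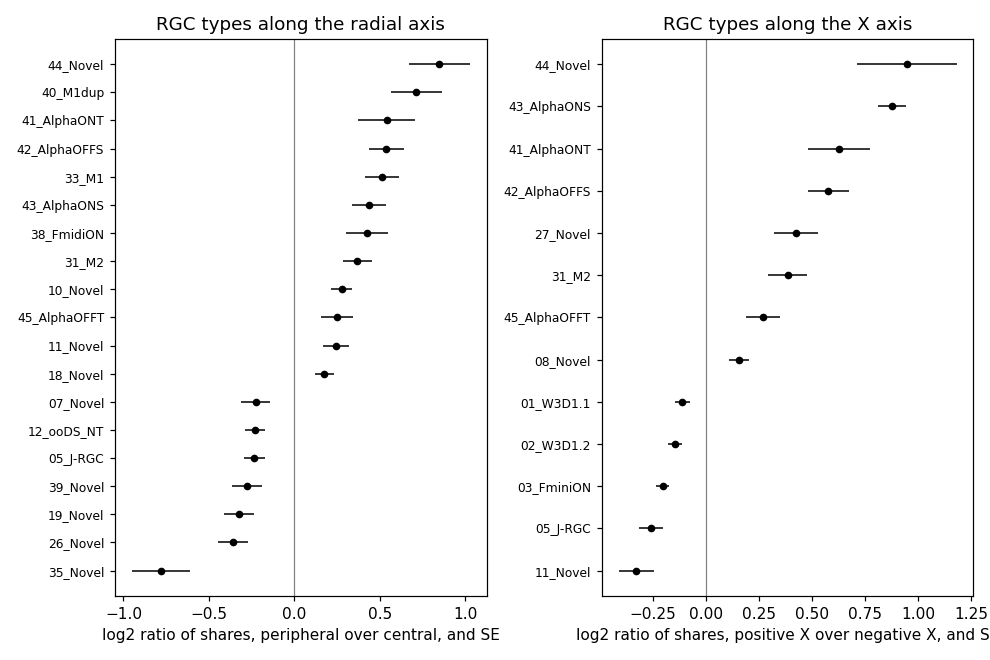
Log2 ratio of the share of each called RGC type between both sides of the radial axis (left) and the X axis (right), fitted by edgeR on cell counts of 5 retinas, with the SE. Type 44_Novel lay highest on both axes, at 0.85 and 0.95. It held 314 cells, 78 of them central and 102 at negative X, and its leading genes stand on the microglia, amacrine and endothelial lists.

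Within single RGC types, Fxyd6 was the gene called in most types from centre to periphery. It was higher peripherally in 26 of the 37 types tested and lay above 0 in all 37, with a median log2 change of 0.51. Spc25, a kinetochore gene, was higher in 17 types, Gngt1 in 11, Sparc in 9 and the rod transducin gene Gnat1 in 7, while the protocadherin gene Pcdh8 was lower in 7 and the synaptic vesicle gene Sv2c in 6. Slide and section blocks were not run within types, and over all RGCs Gngt1 and Pcdh8 lost their call with either block. Single pairs with large changes were Isl2 in 43_AlphaONS (-1.30 ± 0.19), Penk in 42_AlphaOFFS (-1.32 ± 0.26), Cdkn1c in 33_M1 (1.00 ± 0.16), Ptgds in 09_Tbr1_Novel (1.02 ± 0.20) and Lmo2 in 27_Novel (1.07 ± 0.27). In 31_M2, 16 genes were lower peripherally, among them the astrocyte markers Pax2 (-1.22 ± 0.17) and S100b (-1.04 ± 0.15), the Müller glia markers Slc1a3 (-1.30 ± 0.21) and Sox9 (-1.12 ± 0.21), and Cp (-1.23 ± 0.17), and Nell1 was the only gene higher. Without the M2 cells that held Pax2, S100b lay at -0.24 ± 0.13, Slc1a3 at -0.21 ± 0.25, Sox9 at 0.0058 ± 0.31 and Cp at -0.09 ± 0.19, none of them called. In edgeR 211 of 9572 type-gene pairs were called, 149 higher and 62 lower. The rod-marker share over all RGCs was 0.203% ± 0.079 peripherally and 0.157% ± 0.078 centrally, the Müller-marker share 0.601% ± 0.10 and 0.525% ± 0.084, and the endothelial share 0.0359% ± 0.0081 and 0.0296% ± 0.0050. Each was higher in 4 of 5 retinas, as were the bipolar, horizontal, cone and pericyte shares. The exact sign-flip test reaches its smallest p of 0.0625 only with all 5 retinas in one direction, so it could not decide here. Within types, Rlbp1 was called higher in 6 and lay above 0 in 35 of 37, and Trpm1 in 2 and 36 of 37. Without retina 1 the count was 420, without retina 2 it was 93, without retina 4 it was 63, without retina 5 it was 117, and it was 2 without the retina as a block.

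**Figure D4:**
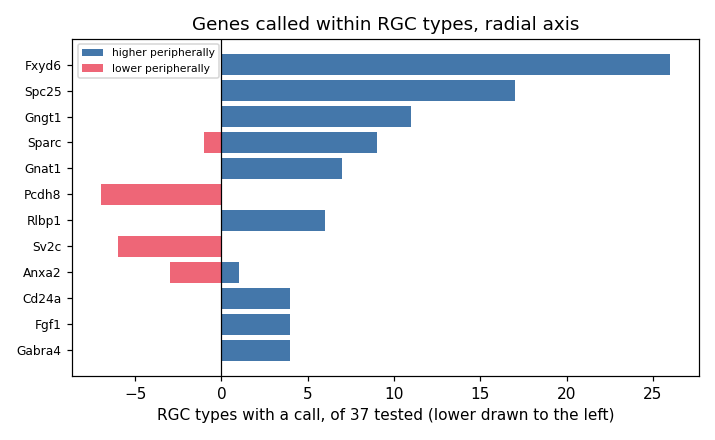
Number of the 37 tested RGC types in which a gene was called higher (right) or lower (left) in the periphery, for the 12 genes with most calls. Fxyd6 led with 26 types.

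Along the X axis, the 4 alpha types and 3 of the 5 alpha-list genes were higher at positive X. The share of 43_AlphaONS was 1.85% ± 0.28 (SD, n = 5) at positive against 1.00% ± 0.13 at negative X, a log2 ratio of 0.88 ± 0.07 (SE), and 41_AlphaONT (0.63 ± 0.15), 42_AlphaOFFS (0.58 ± 0.10), 45_AlphaOFFT (0.27 ± 0.08), 31_M2 (0.39 ± 0.09), 27_Novel (0.42 ± 0.10) and 44_Novel (0.95 ± 0.23) were also higher. Lower at positive X were 11_Novel (-0.33 ± 0.08), 05_J-RGC (-0.26 ± 0.06), 03_FminiON (-0.20 ± 0.03), 02_W3D1.2 (-0.15 ± 0.03) and 01_W3D1.1 (-0.11 ± 0.03). Spp1 was the most changed gene, at 1.77 ± 0.24 against 1.15 ± 0.12 puncta per cell (log2 0.56 ± 0.05), followed by Etv1 (0.41 ± 0.08), the cell cycle inhibitor gene Cdkn1c (0.34 ± 0.06), Prkcq (0.34 ± 0.08), Fxyd6 (0.28 ± 0.05) and the calcium buffer gene Pvalb (0.28 ± 0.06). On the lower side stood Car3, a carbonic anhydrase gene (-0.26 ± 0.05, but 0.04 ± 0.06 with the section as a block), Tafa1 (-0.24 ± 0.05), Ppp1r17 (-0.22 ± 0.04), Cacna1e (-0.19 ± 0.05), Lypd1 (-0.17 ± 0.04) and Foxp2 (-0.16 ± 0.04).

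The file names no anatomical direction for this axis. The Opn1sw share of cone opsin puncta was 14.01 percentage points higher at positive X in retina 3, and lower at positive X in the other retinas. Whether X runs the same way in all 5 retinas is therefore open. In edgeR 30 of 300 genes were called, 19 higher and 11 lower. The named genes also included Prox1 (0.25 ± 0.06), Opn4 (0.25 ± 0.05), Scn4b (0.25 ± 0.05), Ctxn3 (0.24 ± 0.03), Eomes (0.22 ± 0.05) and Igfbp5 (0.21 ± 0.04) on the higher side and Scn7a (-0.14 ± 0.04), Cpne4 (-0.14 ± 0.03), Scn3b (-0.13 ± 0.03), Cacng5 (-0.12 ± 0.03) and Grin2b (-0.09 ± 0.02) on the lower. Of the 5 alpha genes 3 were higher (Spp1, Scn4b, Nefh), of the 4 ipRGC genes 2 (Opn4, Eomes), and of the 3 Foxp2-list genes 2 were lower, with the same counts adjusted over the list alone. Among the channel-named genes 1 was higher and 4 lower, and 1 and 2 adjusted over the list alone. Of the 6 Müller glia markers Apoe was higher (0.21 ± 0.05), and the Müller-marker share was 0.601% ± 0.11 at positive and 0.533% ± 0.054 at negative X, higher in all 5 retinas (exact sign-flip p = 0.0625). At the same p, astrocyte markers were higher at positive X in all 5 retinas (0.138% ± 0.017 against 0.128% ± 0.011), and amacrine markers lower (4.08% ± 0.083 against 4.15% ± 0.070). With the same mix of types on both sides limma called 4 genes, Fxyd6 (0.28 ± 0.05), Spp1 (0.20 ± 0.03), Nefh (0.13 ± 0.02) and Car3 (-0.25 ± 0.04). In edgeR on cell counts 13 types were called, 8 higher and 5 lower, and 14 types moved one way in all 5 retinas (exact sign-flip p = 0.0625 each). Within types 26 of 9236 type-gene pairs were called, 17 higher and 9 lower: Cdkn1c in 33_M1 (1.35 ± 0.15), Ctxn3 in 45_AlphaOFFT (0.71 ± 0.11), Calb1 in 23_W3D2 (-0.56 ± 0.09) and Ppp1r17 in 13_Novel (-0.30 ± 0.04) among them, with Spp1 higher in 5 types. The gene count was 11 without retina 1, 2 without retina 2, 6 without retina 3, 9 without retina 4 and 1 without the retina as a block, while DESeq2 called 47. With the slide within retina as a block 22 of the 30 genes stayed called, without Car3 (-0.07 ± 0.05), Prox1 (0.16 ± 0.08), Igfbp5, Nefh, Foxp2, Cacna1e and Grin2b among the genes named here. With the section as a block 18 stayed called: Prox1 fell to 0.03 ± 0.08, Prkcq to 0.14 ± 0.10, Etv1 to 0.24 ± 0.11, Igfbp5 to 0.11 ± 0.08, Apoe to 0.05 ± 0.06 and Nefh to 0.09 ± 0.05, while Opn4 (0.33 ± 0.12), Lypd1 (-0.17 ± 0.08), Foxp2 (-0.11 ± 0.06) and Grin2b (-0.08 ± 0.03) lost their call with the same sign. Both blocks were added after seeing the data. With the section as a block 11 of the 13 types stayed called, without 02_W3D1.2 and 08_Novel. The type count fell to 4 without retina 1, 6 without retina 2 and 3 without retina 4, and the pair count was 10 without retina 1, 11 without retina 2, 60 without retina 3, 11 without retina 4 and 101 without retina 5.

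**Figure D5:**
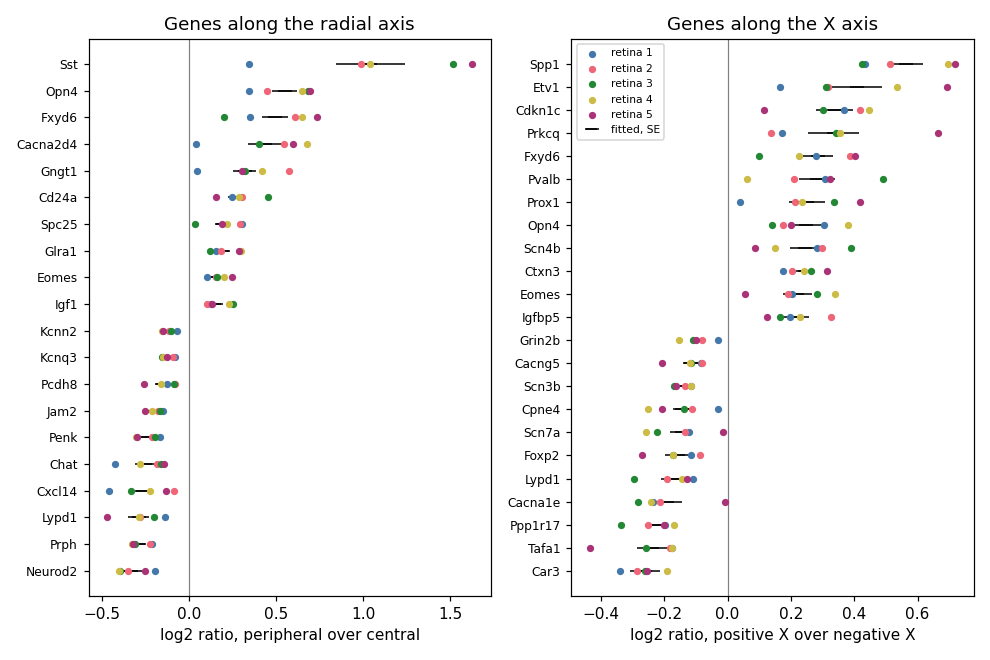
Log2 ratio of each named gene between both sides of the radial axis (left) and the X axis (right), per retina (points) and fitted by edgeR with its SE (black). Opn4 and Fxyd6 lay above 0 in every retina on both axes.

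Along the Y axis, no gene, type or type-gene pair was called by edgeR with the retina as a block and the planned filter. Other edgeR settings gave calls: 11 types without that block, 3 genes and 3 types in the outermost regions, 4 pairs with no filter on low counts, and 112 genes and 19 types with the section as a block. The largest gene differences with one direction in all 5 retinas included Vip, which encodes vasoactive intestinal peptide (0.79 ± 0.14), and Slc1a3, a glial glutamate transporter (0.22 ± 0.04), toward positive Y, both with an adjusted p of 0.165. Type 31_M2 made up 1.85% ± 0.16 of RGCs at positive and 1.30% ± 0.30 at negative Y, 37_Novel 0.754% ± 0.067 and 0.563% ± 0.052, and 28_FmidiOFF 1.23% ± 0.16 and 1.53% ± 0.13, each in one direction in all 5 retinas (exact sign-flip p = 0.0625). The 3 genes of the Foxp2 list gave 0 calls over the panel in edgeR and 3 lower adjusted over the list alone. For genes, 0 of 300 passed against 29 at an unadjusted p under 0.05, and DESeq2 called 6. For types, edgeR on cell counts called 0 of 45 against 16 unadjusted and 6 by DESeq2, and 8 types moved one way in all retinas. For pairs within types, 0 of 9689 passed against 1114 unadjusted and 14 by DESeq2. Without retina 5 the counts were 0 genes, 9 types and 142 pairs, without retina 3 they were 2 genes, 6 types and 7 pairs, and without retina 2 there was 1 pair. Types moving one way numbered 19 without retina 5 and 14 without retina 3.

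Between retinas the rod channel gene Cnga1 varied most on the panel. Its CV over retinas was 51.0%, with 43.2% for Rpgrip1, 40.7% for Scgn and 40.5% for Gsg1, and 1.37% for Kcnip1. Markers of other cells held 4.12% ± 0.079 (amacrine), 1.34% ± 0.050 (horizontal), 0.613% ± 0.094 (bipolar), 0.566% ± 0.075 (Müller glia), 0.184% ± 0.072 (rod), 0.133% ± 0.012 (astrocyte), 0.0425% ± 0.011 (cone), 0.0329% ± 0.0059 (endothelial), 0.0202% ± 0.0024 (microglia) and 0.0173% ± 0.0035 (pericyte and smooth muscle) of all puncta (SD, n = 5). Some of these marker genes also led RGC types, such as Ndnf in 22_M5 (3.97) and Calb1 in 24_Novel (3.67).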

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

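The rule for this part was set before the data were examined. The sets it ran over included the shares of the type families, which were chosen after the data were seen. Type shares, position differences of named genes and other sets of 5 retinas were searched for a single retina far from the others. Of 108 such sets 3 held one. Chance gives about 1 in 20 for sets not chosen by their values. The named genes were chosen for a call and for one direction in every retina, so that rate does not hold for them.

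Retina 3 had the lowest shares of a pair of types led by Penk with Neurod2 next. Type 20_Novel made up 0.937% of its RGCs, with 1.16% in the next retina, and 19_Novel 0.830%, with 1.099% in the next. Retina 3 is also the retina with fewest cells. No biological explanation was tested.

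Cacna1e, the calcium channel gene that led 11_Novel, was lower at positive X in the fit. In retina 5 its log2 difference was -0.0082, with -0.21 in the next retina. No biological explanation was tested.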

How the results depend on the processing

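The fits with cells of 200 puncta or more, slide or section blocks, the same mix of types and the edgeR and DESeq2 fits of cell counts are tests chosen only after the result was seen. Over the named genes, types and pairs and the counts, 3862 results stayed on their side under an alternative, 476 lost their call with the same sign, 71 moved and 2 reversed. This total pools unlike parts. Without each retina in turn, all 24 named genes of every gate kept their call, against 2 of 20 radial and 2 of 23 X genes. Of the called types 10 of 19 radial and 3 of 13 X types did, and of the named pairs within types 12 of 24 radial and 2 of 19 X pairs.

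The gates and type markers were the steadiest: leaving out each retina gave 187 to 200 genes for Opn4, 214 to 225 for Foxp2 and 8615 to 9091 type-gene pairs. With no replicate block the Eomes gate called 134 genes and the Spp1 gate 119. That alternative adds the spread between retinas to the error. With no replicate block the radial axis called 1 gene, 5 types and 2 pairs within types, X 1 gene, 8 types and 0 pairs, and Y 11 types. The 0 pairs along X under edgeR compare with 960 at an unadjusted p under 0.05 with the block and 21 by DESeq2.

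DESeq2 called 44 genes along the radial axis, 6 along Y and 47 along X, 12 types along the radial axis and 6 along Y, and 14 pairs within types along Y. The outermost regions alone gave 12 radial genes, 3 genes and 3 types along Y. With the section as a block, 52 radial genes, 112 Y genes, 51 X genes and 19 Y types were called, and Car3 along X turned to 0.043. That block treats sections of 1 retina as replicates, so its calls say nothing about the spread between retinas. With the same mix of types, 4 X genes were called, and with no filter on low counts 4 pairs within types along Y. The other causes were not tested.

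Leaving out each retina gave 2 to 53 radial genes, 0 to 2 Y genes and 2 to 43 X genes. For types on cell counts it gave 12 to 21 along the radial axis, 0 to 9 along Y and 3 to 16 along X, and 8 to 19 types moving one way along Y. Within types it gave 63 to 420 radial pairs, 0 to 142 along Y and 10 to 101 along X. The single retinas were these: for radial genes 53 without retina 1, 3 without retina 2, 2 without retina 4 and 10 without retina 5; for X genes 11 without retina 1, 2 without retina 2, 6 without retina 3 and 9 without retina 4. For types, 12 without retina 4 (radial), 4, 6 and 3 without retinas 1, 2 and 4 (X), and 6 and 9 without retinas 3 and 5 (Y). For pairs, 420, 93, 63 and 117 without retinas 1, 2, 4 and 5 (radial), 10, 11, 60, 11 and 101 without retinas 1 to 5 (X), and 1, 7 and 142 without retinas 2, 3 and 5 (Y). Along Y 2 genes were called without retina 3, and types moving one way numbered 14 and 19 without retinas 3 and 5.

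In cells of 200 puncta or more, alpha types held 5.54% of RGCs, the Tbr1 types 8.23%, the W3 types 16.8% and the other types 41.7%. Of the W3 types, 01_W3D1.1 had a median of 186.2 puncta, which lies under this minimum. The medians of 02_W3D1.2 (299.4), 06_W3B (319) and 23_W3D2 (355.7) lie over it. In the cells as deposited the log2 odds ratio of Eomes with Neurod2 was 0.013. The cause was not tested. Depth limits co-detection, since thinning leaves 100 puncta for 300 genes.

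The minimums of 10, 20 and 40 puncta and the panel variation over all cells change nothing here, as every cell holds at least 100 puncta, and were not run. The class shares, the clustering resolutions and RGCs against other cells could not be run on a table of RGCs alone.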

Other observations

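The Y turns of retinas 3 and 5, the draws of equal cell numbers, the test for astrocytes or their RNA in M2 cells, the exchanges of sides and the draws of type labels are tests chosen only after the result was seen.

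RGCs of 1 type kept apart from each other in 35 of the 45 types. Pairs of cells of the same type whose centres lay 10 to 20 units apart within a section were 0.410 ± 0.038 (SD, n = 5) times as frequent as with shuffled type labels, from 0.372 to 0.460 over the retinas. The ratio was 0.639 at 20 to 30 units, 0.727 at 30 to 40 and 1.02 at 60 to 100. By type, 35 lay below all 100 shuffles at 10 to 20 units, 20_Novel among the lowest at 0.0617, and 9 neither below nor above all. Type 40_M1dup lay above all of them at 2.06, on 18 pairs, and 41_AlphaONT (1.31), 45_AlphaOFFT (1.23), 44_Novel (1.205) and 27_Novel (1.02) also over 1. A cell segmented into pieces would raise close pairs of one type. Under 10 units the ratio was 0.171 with all types pooled, which argues against it for the pooled pairs only. No ratio by type was taken under 10 units, so pieces within 40_M1dup or the other types over 1 were not tested. Which cells were kept is not given, so pieces removed before deposit would not show. Spacing within those 35 types may be a property of the tissue, a hypothesis found and tested on the same data. The units of position are not stated.

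Along Y, retinas 1, 2 and 4 had like profiles of type shares (Spearman 0.82, 0.85 and 0.87), while retina 5 lay at -0.16 to -0.22 and retina 3 at 0.06 to 0.14 against them, with -0.14 between both. A candidate explanation is that retina 5 lies turned. Cone opsin puncta, whose Opn1sw share is graded between dorsal and ventral retina in mice, gave differences between positive and negative Y of -10.1, -14.4, -0.034, -10.7 and 11.2 percentage points in retinas 1 to 5 (15355 puncta). The value of 11.2 in retina 5 (95% counting interval 7.23 to 15.1) goes with a turn. Along the radius, periphery minus centre, the differences were -5.60, 3.82, 3.48, 6.25 and -14.7 percentage points in retinas 1 to 5. A difference of this size in retina 5 was therefore not particular to Y. The table holds RGCs alone, so these puncta lay in cells called RGCs and do not measure cones directly. A turn alone would also mirror the profile. The type shares of retina 5, at -0.18 on average, fall short of that, as do its genes (-0.29, -0.01 and -0.12), so a turn stays open, as in retina 3 (-0.034, -3.98 to 3.91). Fewer cells by number alone are argued against, since with equal numbers the lowest correlation among retinas 1, 2 and 4 was still 0.700 on average. These draws took cells at random, so they cannot speak to missing parts of a retina. Retinas 3 and 5 had 7 and 5 sections and median radii of 0.49 and 0.47. Retinas 1, 2 and 4 had 10, 10 and 9 sections and median radii of 0.67, 0.60 and 0.63. A mislabelled retina and turns other than along Y were not tested. No biological explanation was tested.

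The opsin differences along Y argue against positive Y being the dorsal side in all 5 retinas (mean -4.81, opposite in retina 5). Along X they were -4.04, -4.36, 14.01, -1.53 and -8.88 (mean -0.957), which argues against positive X being dorsal in all 5.

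Some of the cells called M2 held many glial puncta, a larger share of them in the centre than in the periphery. Of 2002 M2 cells, 153 held at least 2 puncta of the astrocyte gene Pax2, 11.8% of central and 5.83% of peripheral M2 cells. These held 8.38 RGC-marker puncta per cell against 20.4 in M2 cells without Pax2, 0.627 against 5.70 puncta of Opn4 with Tbx20, and 94.1 against 7.89 puncta of the other genes lower in the periphery. Without any Pax2-holding cell, the median log2 change of the 13 other lower genes that could be tested went from -0.87 to -0.071, and Anxa2 alone stayed lower (-0.71, adjusted p 0.021, edgeR). Pax2 is itself one of the lower genes, so this does not show whether M2 cells make them. RNA from astrocytes beside whole M2 cells would leave their RGC markers near the level of the others, and the ratio of 0.410 ± 0.078 (SD, n = 5), at most 0.530, argues against it. Astrocytes called M2 stay open, as the ratio lay under 0.5 in 4 retinas but not in retina 3, and cells segmented from parts of both were not tested. Of the astrocyte markers S100b is also on the N-RGC list. Apart from M2 cells making these transcripts, which leaving out the Pax2-holding cells could not decide, no biological explanation was tested.

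Sides were exchanged within retinas in all 16 ways, too few for a share under 0.05. The real split called as many as any in 1 of 16 for each gate: 199 for Opn4, 234 for Eomes, 230 for Foxp2, 214 for Neurod2 and 212 for Spp1, with 0 the highest of the others. Along the radial axis, 1 of 16 reached the 20 genes (highest other 2), 1 of 16 the 19 types (14, with retina 3 exchanged) and 1 of 16 the 211 pairs within types (21). Along X, 1 of 16 reached the 30 genes (0), 1 of 16 the 13 types (0) and 1 of 16 the 26 pairs (7). Along Y, all 16 reached the real counts of 0 genes, 0 types and 0 pairs in edgeR (29, 16 and 1114 unadjusted, 6, 6 and 14 by DESeq2). The highest of the others along Y were 7 genes and 227 pairs with retinas 3 and 5 exchanged and 7 types with retina 5 exchanged. With type labels drawn within retinas, 1 of 40 draws, the real one, reached 9278 pairs (highest other 367), and 1 of 40 each the genes of the families: ipRGC 255 (16), alpha 236 (36), F 224 (18), Tbr1 199 (45), ooDS 235 (34) and W3 222 (29). Labels that rest on the same genes would give this by construction, so the draws do not exclude chance.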
